A study of Mus musculus with 12 samples.

How the data were processed

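Liver RNA from male mice of 2 related strains was measured on whole-transcript Affymetrix arrays. KK.Cg-Ay/J (KKAy) mice carry the yellow allele of agouti on the KK background and are an obese, diabetic model. KK-a/a (KKa) mice of the same background carry the nonagouti alleles. Both strains were sampled at 6, 16 and 42 weeks, which gave 6 groups of 2 arrays and 12 arrays in all. Per the labels, each group had 4 mice, their livers were pooled in equal weight, and 2 replicates were measured. Whether the 2 arrays of a group came from separate pools, separate RNA extractions or the same RNA is not given in the sources used here. The p-values below therefore measure only the spread between these arrays, which may be technical. All mice ate a chow with 13.2% fat and 19.3% protein, and 300 ng of RNA per sample was labelled with a sense-target kit. The time of day of collection and the array batches are not given in the sources used here, so age and any batch that follows age cannot be told apart. The 16-week KKa arrays carry sample codes of another pattern than the other arrays, with no reason stated.

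The deposited value table holds log2 expression for 35556 probe sets on each of the 12 arrays. Per the submitters' processing notes the authors made it with RMA in Affymetrix Expression Console, which corrects background, quantile-normalizes the arrays and summarizes the probes of a probe set. Versions and the genome build are not given in the sources used here. The authors also deposited 3 comparison tables, one for each age, with log2 group averages, SDs, a signed linear fold, a p-value and a false discovery rate (FDR) for each probe set listed. In the deposited tables every listed probe set had a p-value of at most 0.05 and an absolute fold of at least 1.2, so they held 1515, 3904 and 5403 probe sets at 6, 16 and 42 weeks. The program and test behind these p-values are not given in the sources used here. The log2 averages in the authors' tables lay within 0.058 of the group means of the value table.

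Gene names came only from the authors' comparison tables. They listed 9156 of the 35556 probe sets; 8008 of these named 1 gene (7628 distinct genes), 474 named several and 674 named none. The other 26400 probe sets (74.2%) are unnamed here. A gene could thus be named only if its probe set differed between the strains at an unadjusted p-value up to 0.05 at some age. The gene lists, the counts adjusted over a list alone and the alternative of probe sets naming 1 gene carry that selection. Symbols were updated through RefSeq accessions for 6690 probe sets and through a symbol in the reference for 1051, and 267 kept the name in the file. Of 7717 named probe sets with a position, 7618 (98.7%) overlapped the gene of that symbol in the GRCm38 table. The other 99 may read a copy or pseudogene elsewhere and none of them is named in the results, but 4 stand for list genes, 2 in oxidative phosphorylation and 1 each in the PPARα and glycolysis lists. Coordinates are printed as the authors' tables give them. No probe set was named from its identifier, and probe sets of near-identical genes (the Cyp2c, Cyp4a, Mup and alpha-globin families) may read more than 1 gene.

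Probe sets were tested in R 4.3.3 with limma 3.58.1, by lmFit and eBayes on the deposited log2 values with a mean for each group. All 12 arrays entered 1 fit, so that the groups shared the estimate of spread (6 residual and 8.59 moderated degrees of freedom). The p-values are two-sided and were adjusted by the Benjamini-Hochberg method over all 35556 probe sets of a comparison, and a probe set was called at an adjusted p of 0.05. Errors are standard errors of the log2 change from the fit unless an SD is named. The strains were compared at each age, successive ages within each strain, and the strain difference between ages. In a strain comparison, rose and fell mean higher and lower in KKAy than in KKa. Comparisons that use the same arrays, such as the 2 age steps of a strain or the differences at 42 weeks, share chance values. A comparison of the strains averaged over the 3 ages was added after seeing the data. No p-value is given for the difference between replicate arrays of a group.

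The rule for named genes, the gene lists, the fit and the alternatives were fixed before the data were examined, except where stated. The rule took the 10 largest positive and 10 largest negative log2 changes in each strain comparison among called probe sets naming 1 gene whose arrays did not overlap between groups. For age comparisons and differences it took the 5 largest each way, with no condition on overlap for the differences. Transcripts with no established name, such as predicted genes, microRNAs, small nucleolar RNAs and 5S ribosomal RNAs, were left out of this choice and counted. Up to 3 called members each way of each gene list and the agouti locus genes were added, along with list members described as not called. In the age steps, called list members were named beside their list after their values were seen. The genes of the averaged comparison were chosen as in a strain comparison. Some genes that the rule would name are not reported here, and counts include them.

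The 30 gene lists held 662 entries for 652 distinct genes, of which 338 had a named probe set. A list was tested when at least 3 of its genes were named, which left 29, against the 7628 named genes, with the probe set of highest mean standing for a gene that had several. The test was limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 29 lists. Camera with an estimated correlation and limma's fry, which tests whether members move one way on balance without comparing them with other genes, were run beside it. Results of fry are given below only for the differences between ages. Tests of the lists in the differences between ages were added after seeing the data.

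The alternatives were median centring of the arrays, cyclic loess, a filter keeping the 50% of probe sets with the highest mean, only probe sets naming 1 gene, an intensity trend in the variance model, array weights, a fit to the compared groups alone, the replicate number as a block, a log2 change of at least 1, an adjusted p of 0.01, and each array left out in turn. A further alternative, chosen after seeing the data, left out 6612 probe sets whose identifiers are lower than any in the authors' tables. None of these was listed there, although 551, 780 and 1010 of them passed the tables' p-value and fold limits in the present fit at 6, 16 and 42 weeks. What they target is not given in the sources used here, and the fit keeps them.

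The fit was tested on simulated data with the real means and spreads of 35556 probe sets, 200 of them changed by 0.5, 1 or 2 on the log2 scale. Values were drawn as independent between probe sets and arrays, with the spread between arrays of a group. The simulation thus does not cover effects shared by an array or a pool. In the strain comparison at 6 weeks the fit called 9.1%, 51.2% and 90.5% of these sizes with 3 false calls. At 16 weeks the shares were 6%, 47.7% and 82.4% with 7 false calls, and at 42 weeks 12.9%, 62.1% and 88.9% with 4. From 6 to 16 weeks they were 1.6%, 47.1% and 81.8% with 2 in KKa and 6.5%, 68.7% and 85.9% with 5 in KKAy. From 16 to 42 weeks they were 4.2%, 57.6% and 87.1% with 7 in KKa and 4.2%, 43.2% and 94.4% with 4 in KKAy. For the difference of the strain differences they were 0%, 19.2% and 79% with 4 between 6 and 16 weeks, 0%, 20% and 69.5% with 7 between 16 and 42 weeks and 0%, 9.4% and 73% with 2 between 6 and 42 weeks. A simulated shift of 0.5 in 16 of the 7628 named genes, with genes drawn as independent, was called in each of the 7 strain and age comparisons, with 0 other lists called. With an estimated correlation its adjusted p lay between 0.00173 and 0.00814. The number of arrays limits the precision: the median standard error of a log2 change was 0.157 in a strain or age comparison and 0.222 in a difference of differences. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.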

Results

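Expression was measured in pooled liver of KKAy and KKa mice at 6, 16 and 42 weeks, with 2 arrays per group. Median log2 values of the 12 arrays lay between 4.738 and 4.883, and the arrays of a group correlated at 0.9833 to 0.9912 over probe sets. On 9 of the 12 arrays the highest correlation was with the other array of the group, and the exceptions were both 6-week KKa arrays and 1 KKAy array at 6 weeks. Across groups the SD between arrays, as a root mean square over probe sets, was 0.227 to 0.309, highest in KKAy at 42 weeks. Lower quartiles of the arrays lay between 3.260 and 3.440. Of the genes named below, Trdn, Zfp972, Sult1e1, Hao2, Rnase2a and Chil6 had at least 1 group mean under those of its arrays, so the size of their changes is uncertain. For Sult1e1 this held in all 6 groups, with means of 1.95 to 3.26.

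The agouti gene, whose yellow allele defines KKAy, was higher in KKAy at each age. Agouti (a, chromosome 2, 155013531 to 155051011) encodes a paracrine antagonist of melanocortin receptors that is normally restricted to skin. Its log2 value was 6.78 to 7.06 on the 6 KKAy arrays and 5.20 to 5.51 on the 6 KKa arrays, so every KKAy array lay above every KKa array. By limma the increase was 1.67 ± 0.13 at 6 weeks (3.19-fold, adjusted p = 0.0315), 1.49 ± 0.13 at 16 weeks (2.80-fold, adjusted p = 0.0371) and 1.68 ± 0.13 at 42 weeks (3.21-fold, adjusted p = 0.00186), with n = 2 arrays per group. The 6-week call was lost without any 1 of the 4 arrays and the 16-week call without KKa array 2 or either KKAy array, with log2 changes of 1.53 to 1.81 and 1.34 to 1.53, while the 42-week call held without each. Eif2s2, a translation initiation factor subunit encoded at chromosome 2, 154871410 to 154892906, was lower in KKAy at 42 weeks, with a log2 change of -1.14 ± 0.11 (adjusted p = 0.00377). Its log2 changes at 6 and 16 weeks were both -0.65 ± 0.11, with limma adjusted p = 0.522 and 0.0937. The authors' deposited table gave it an FDR of 0.0377 at 16 weeks. The log2 value of Eif2s2 was 5.68 to 6.24 on the 6 KKAy arrays and 6.34 to 6.92 on the 6 KKa arrays. Every KKAy array thus lay below every KKa array. The differences of these strain differences between ages gave adjusted p = 0.174 or above for both genes in limma. The 2 other genes of this list had no probe set naming them alone. A further probe set at chromosome 2, 154791157 to 154867247, carries agouti's name beside another gene's and was assigned to neither. It ends before the interval given for agouti begins, so it need not read agouti. Averaged over the ages, a comparison added after seeing the data, this probe set was lower in KKAy at -0.74 (limma adjusted p = 0.0207).

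**Figure D1:**
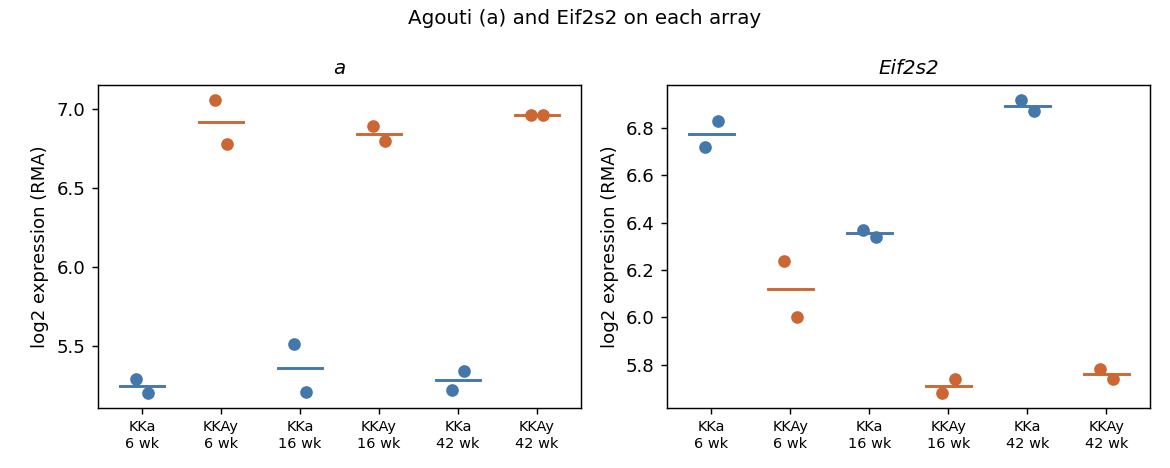
Log2 expression of agouti (left) and Eif2s2 (right) on each array, by strain (KKa blue, KKAy orange) and age; points are arrays and lines are means of the 2 arrays of a group. Agouti lay at 6.78 to 7.06 in KKAy and 5.20 to 5.51 in KKa.

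At 6 weeks, labelled as a pre-developing stage, agouti was the only probe set called between KKAy and KKa liver. Genes of cholesterol synthesis had higher values in KKAy as a group: all 21 named members had a positive log2 change, with a median of 0.43. Among them were the epoxidase Sqle at 0.92 ± 0.44 and the synthase Hmgcs1 at 0.75 ± 0.33, neither called alone (limma adjusted p = 0.921 for each). The list rose by camera (adjusted p = 4.11e-05), a call lost at adjusted p = 0.769 with an estimated correlation. The interferon response list also rose (adjusted p = 0.000846, and adjusted p = 0.731 with an estimated correlation), with 15 of 17 changes positive, such as the guanylate-binding protein Gbp2 at 0.67 ± 0.17 and the antiviral gene Ifit1 at 0.67 ± 0.28. The female-biased liver gene list rose as well (adjusted p = 0.000846, and adjusted p = 0.278 with an estimated correlation). Adjusted over the list alone, 4 of its 12 members were higher against 0 over all probe sets: Cyp4a14 at 1.18 ± 0.34, Acot3 at 1.15 ± 0.26, Abcd2 at 1.12 ± 0.26 and Hao2 at 0.85 ± 0.22. All 4 act in fatty acid metabolism, and Cyp4a14 and Acot3 also belong to the PPARα list. Adjusted over the list alone, no gene of the cholesterol or interferon lists was called, the same count of 0 as over all probe sets. In all, 1878 probe sets had an unadjusted p under 0.05. Limma's count of 1 became 0 without KKa array 1, KKa array 2 or KKAy array 2 and 0 with the replicate number as a block, and without KKAy array 1 the 1 call was another probe set than agouti.

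At 16 weeks the largest difference was in Cyp4a14, a fatty acid ω-hydroxylase and PPARα target, at 30.8-fold higher in KKAy. Its log2 value was 9.38 ± 0.20 (SD, n = 2 arrays) against 4.44 ± 0.56 in KKa, a change of 4.95 ± 0.34 with a limma adjusted p of 0.00792. Hsd3b5, a male-specific liver hydroxysteroid dehydrogenase, fell by 1.47 ± 0.14 on the log2 scale (2.77-fold, adjusted p = 0.0371). With agouti and 1 probe set that names no single gene, these were the 4 calls, 2 higher and 2 lower, and 4491 probe sets had an unadjusted p under 0.05. The call of Cyp4a14 was lost without KKAy array 1 or KKAy array 2, at log2 changes of 5.09 and 4.80, and that of Hsd3b5 without any 1 of the 4 arrays, at -1.56 to -1.38.

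Gene groups of hepatic lipid metabolism separated at 16 weeks. All 21 cholesterol synthesis genes had negative log2 changes with a median of -0.78, among them the farnesyl diphosphate synthase Fdps at -1.55 ± 0.33 and Sqle at -1.51 ± 0.44. This list fell by camera (adjusted p = 1.75e-09, and adjusted p = 0.364 with an estimated correlation). Adjusted over the list alone 16 of its genes were lower, against 0 over all probe sets. Counts adjusted over a list alone are raised by selection, since named genes differed between these strains at some age. For scale, a fit to the 8008 probe sets naming 1 gene called 1210 at this age. De novo lipogenesis fell too (adjusted p = 9.05e-06, and adjusted p = 0.364 with an estimated correlation), with 9 of 16 genes lower adjusted over the list alone and 0 over all. Its members included fatty acid synthase Fasn at -1.73 ± 0.31, Mid1ip1, a regulator of acetyl-CoA carboxylase, at -1.25 ± 0.25 and the elongase Elovl6 at -1.18 ± 0.30. The list of fatty acid oxidation and PPARα targets rose (adjusted p = 0.000197, and adjusted p = 0.364 with an estimated correlation). Adjusted over the list alone 12 of its 22 genes were higher and 1, Fabp1 at -0.40 ± 0.13, was lower, against 1 higher over all. Cyp4a31 stood at 2.72 ± 0.34 and the carnitine palmitoyltransferase Cpt1a at 0.73 ± 0.14. Lipid droplet and fatty acid uptake genes rose at an adjusted p of 0.0495 (adjusted p = 0.364 with an estimated correlation), with 3 of 13 higher adjusted over the list alone and 0 over all. This call was lost after median centring (adjusted p = 0.0559) and cyclic loess (adjusted p = 0.0755). The fatty acid transporter Cd36 had a change of 2.23 ± 0.78 and the droplet coat gene Plin4 one of 0.91 ± 0.27.

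Acute phase genes, made by hepatocytes in inflammation, had positive changes in all 18 named members at 16 weeks. Serum amyloid Saa2 stood at 3.93 ± 0.80, lipocalin Lcn2 at 3.14 ± 0.65 and orosomucoid Orm2 at 3.02 ± 0.55. The list rose (adjusted p = 1.87e-07, and adjusted p = 0.364 with an estimated correlation), with 15 of 18 higher adjusted over the list alone and 0 over all. Markers of macrophages and Kupffer cells rose (adjusted p = 0.00309, and adjusted p = 0.548 with an estimated correlation). Of these 15 markers 9 were higher and 1, Trem2 at -0.41 ± 0.15, was lower adjusted over the list alone, with 0 over all. Vsig4, Cd5l and Clec4f, markers of resident Kupffer cells, stood at 1.19 ± 0.33, 0.96 ± 0.29 and 0.64 ± 0.17. Female-biased genes rose and male-biased genes fell (adjusted p = 0.00309 and 0.00420, both with adjusted p = 0.261 with an estimated correlation). Adjusted over the lists alone 5 of 12 were higher and 5 of 20 lower, against 1 and 1 over all. Those over all were Cyp4a14 at 4.95, also in the PPARα list, and Hsd3b5. Camera lost the female-biased call in the probe sets of highest mean alone (adjusted p = 0.0563). That list was not tested without Cyp4a14. Of the 12 female-biased changes 10 were positive and 2 negative, among the latter Cyp2c40, with means of 9.86 in KKAy and 10.11 in KKa. Sulfotransferase Sult1e1 stood at 0.89 ± 0.13 and Cyp2b9 at 1.34 ± 0.23, while the male-biased Keg1 stood at -0.64 ± 0.11. All Sult1e1 values at 16 weeks, 1.94 to 2.95, lay under the lower quartiles of their arrays. Amino acid catabolism genes rose (adjusted p = 0.00420, and adjusted p = 0.261 with an estimated correlation), with 4 of 7 higher adjusted over the list alone and 0 over all, among them Oat at 0.90 ± 0.16 and Mat1a at 0.66 ± 0.12. Glycolysis and pentose phosphate genes fell (adjusted p = 0.0110, and adjusted p = 0.491 with an estimated correlation), with 0 called either way.

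The 16-week count of 4 was 124 without the unlisted block of 6612 probe sets, 145 with an intensity trend and 9 after cyclic loess, which split as 2 higher and 7 lower. The authors' deposited table gave an FDR under 0.05 to 124 probe sets at 16 weeks, 82 of them higher and 42 lower. Without KKa array 1 there were 5 calls, 2 of them among the 4, without KKa array 2 or KKAy array 1 there was 1, which was one of the 4 only in the first case, and without KKAy array 2 there were 0.

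At 42 weeks 332 probe sets were higher and 327 lower in KKAy, 659 in all, naming 479 genes. The largest increase was in Moxd1, a monooxygenase-like gene with male-biased liver expression, at 31.3-fold (log2 4.97 ± 0.90, adjusted p = 0.0373). Cxcl1, a chemokine that attracts neutrophils, was 10.5-fold higher (3.39 ± 0.35, adjusted p = 0.00536), and the immediate early genes Egr1 and Btg2 were 8.91-fold and 5.85-fold higher. Cyp2b10, a drug-metabolizing P450 induced through the receptor CAR, was higher in KKAy by 3.00 ± 0.18 (adjusted p = 0.000556). Its means at 16 and 42 weeks were 11.01 and 7.95 in KKa and 11.55 and 10.95 in KKAy. This difference thus came mainly with a fall in KKa. From 16 to 42 weeks 2031 probe sets were called in KKa and 142 in KKAy. Strain differences at 42 weeks can therefore stem from changes in KKa. The growth factor Nrg4 rose 6.99-fold, Tiparp, a target of the aryl hydrocarbon receptor, 6.31-fold and orosomucoid Orm3 6.06-fold. Of 12 probe sets naming triadin (Trdn), 1 was called higher, with KKa values of 2.94 and 1.87 below the lower quartile of those arrays (3.29), and the 11 others had changes of 0.25 to 1.87 with adjusted p = 0.0527 or above. Limma's adjusted p for these 6 genes without one given above lay between 0.00394 and 0.0387. Moxd1 had log2 values of 9.21 and 8.46 in KKAy and 3.91 and 3.83 in KKa, but 5.69 and 9.20 on the KKa arrays at 16 weeks, and its 42-week call was lost without any 1 of the 4 arrays, as were those of Trdn and Orm3. The log2 changes of Egr1, Btg2 and Tiparp were 2.43, 1.89 and 1.72 without KKAy array 1 and 3.88, 3.20 and 3.59 without KKAy array 2, and their calls were lost without either KKa array.

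Among the genes lower in KKAy at 42 weeks were several P450 enzymes. Cyp4a14, higher in KKAy at 16 weeks, had a log2 change of -2.05 ± 0.34 here (limma adjusted p = 0.0295). Cyp2a22 had a log2 change of -2.11, Cyp2c67 of -1.99 and Cyp2c68 of -1.81. Pdk4, which restrains pyruvate oxidation in fasting, fell by 2.12 ± 0.35 (adjusted p = 0.0302). The phosphate transporter Slc34a2 and the kinase-like gene Gask1a fell by 1.81 and 1.87. Without KKAy array 1 and KKAy array 2 the change of Pdk4 was -1.52, no longer called, and -2.72, and without KKa array 1 and KKa array 2 that of Slc34a2 was -1.20, no longer called, and -2.42. Zfp972, on chromosome 2 within 25 Mb of agouti, had a log2 change of -1.95 between values of 1.65 in KKAy and 3.61 in KKa, near the lower end of the arrays' range. Limma's adjusted p for these 6 genes without one given above lay between 0.00189 and 0.0436.

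**Figure D2:**
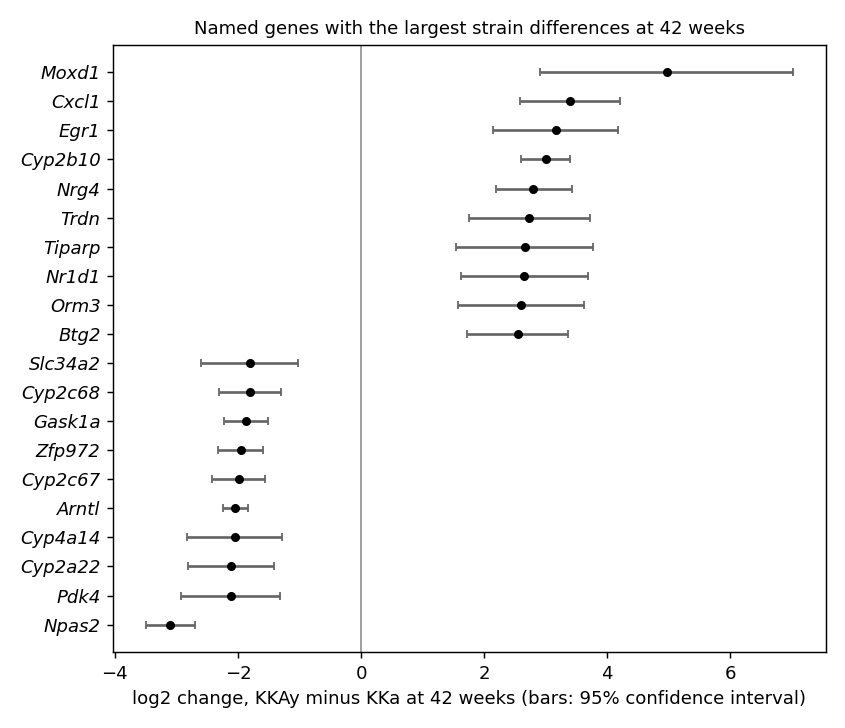
Log2 change (KKAy minus KKa) at 42 weeks of the 20 named genes with the largest called differences; points are estimates from 2 arrays per group and bars are 95% confidence intervals from the limma fit. The changes ran from -3.10 for Npas2 to 4.97 for Moxd1, whose interval was the widest at 2.91 to 7.02.

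Genes of the circadian clock moved in opposite directions at 42 weeks. The transcriptional activators Npas2, Arntl and Clock fell by 3.10 ± 0.18, 2.04 ± 0.09 and 0.67, with adjusted p = 0.000556, 0.000292 and 0.0231 in limma. Cry1 was also lower, with a log2 change of -1.46. The repressors Nr1d1 and Nr1d2 and the output regulator Dbp rose by 2.65 ± 0.45, 1.52 ± 0.17 and 2.36 ± 0.33 (adjusted p = 0.0320, 0.00691 and 0.0186), and Tef and Bhlhe41 were higher by 0.99 and 1.48. The change of Nr1d1 was 1.93, no longer called, without KKa array 1 and 3.37 without KKa array 2, and that of Dbp was 2.96 and 1.76 without KKAy array 1 and KKAy array 2. Of 17 named clock genes 5 were called higher and 5 lower, and adjusted over the list alone 9 were higher and 6 lower. Camera, which tests for a shift one way, gave an adjusted p of 0.689 for the list.

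**Figure D3:**
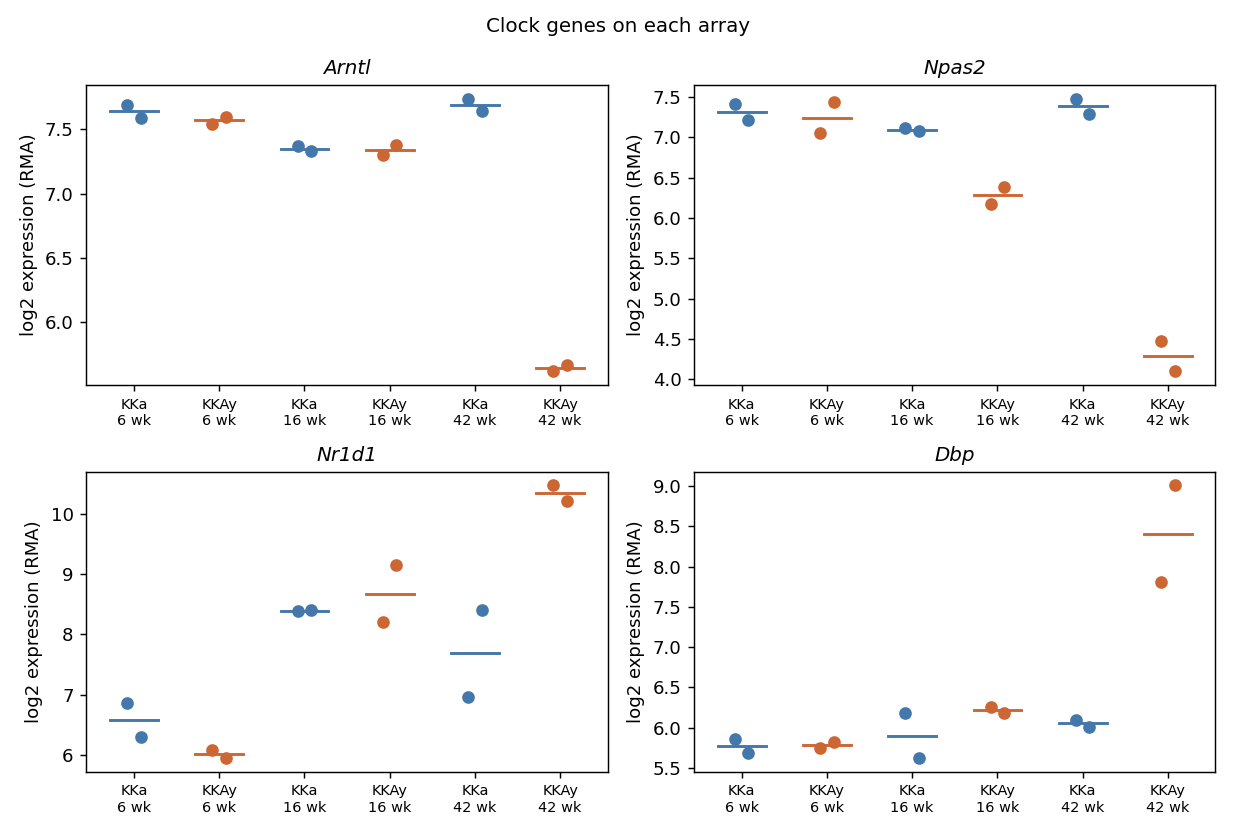
Log2 expression of 4 clock genes on each array, by strain (KKa blue, KKAy orange) and age; points are arrays and lines are group means. Arntl lay at 5.62 and 5.67 on the KKAy arrays at 42 weeks and at 7.30 to 7.74 on the 10 others.

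The cholesterol synthesis list fell again at 42 weeks (adjusted p = 2.14e-05, and adjusted p = 0.768 with an estimated correlation). All 21 changes were negative, 3 genes were called lower over all probe sets and 16 adjusted over the list alone. As at 16 weeks, counts adjusted over a list alone are raised by the selection of named genes. A fit to the 8008 probe sets naming 1 gene called 3258 at 42 weeks. The called genes were the sterol dehydrogenase Nsdhl at -1.78 ± 0.35, Pmvk at -1.20 ± 0.23 and Hsd17b7 at -1.10 ± 0.22. All were lower on KKAy array 1 (log2 values 7.34, 6.26 and 7.74) than on KKAy array 2 (8.62, 6.94 and 8.39). The list tests were not run with an array left out, so the weight of KKAy array 1 in them is unknown. The change of Nsdhl was -1.14, no longer called, without KKAy array 1 and -2.42 without KKAy array 2. Lipogenesis fell (adjusted p = 0.00125, and adjusted p = 0.768 with an estimated correlation), with 3 genes called over all, the acetyl-CoA carboxylases Acaca and Acacb, each at -0.97, and Acss2 at -0.89. Adjusted over the list alone 12 of its 16 genes were lower. The PPARα list also fell (adjusted p = 0.00136, and adjusted p = 0.768 with an estimated correlation), with Pdk4, Cyp4a14 and the thioesterase Acot2 at -1.47 called over all and 9 of 22 lower adjusted over the list alone. Acute phase genes rose (adjusted p = 0.000249, and adjusted p = 0.768 with an estimated correlation). Orm3 at 2.60 and Serpina3n at 0.97 were called over all and 10 of 18 adjusted over the list alone. Neutrophil markers rose (adjusted p = 0.00220, and adjusted p = 0.768 with an estimated correlation), with Retnlg at 1.90 ± 0.19 called over all and 7 of 9 higher adjusted over the list alone. The hours of collection are not given in the sources used here, so their part in these list changes was not tested.

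**Figure D4:**
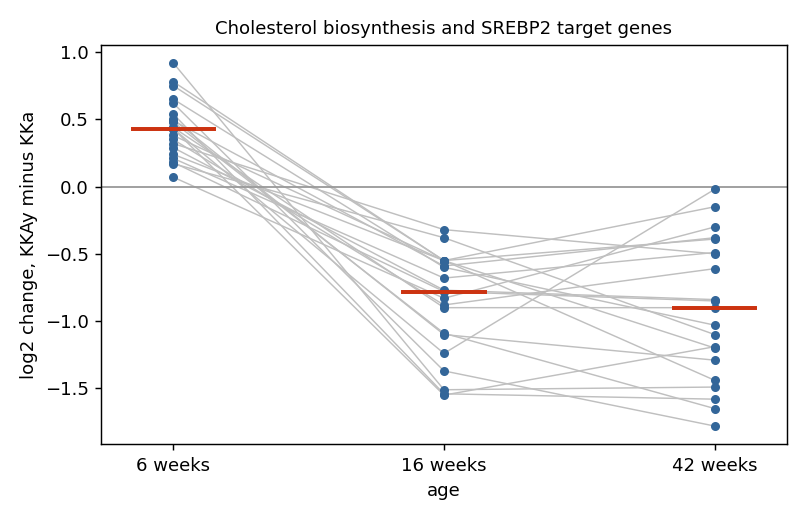
Log2 change (KKAy minus KKa) of the 21 named cholesterol synthesis and SREBP2 target genes at each age; points are genes joined by grey lines, and red bars are medians. The medians were 0.43 at 6 weeks, -0.78 at 16 weeks and -0.90 at 42 weeks.

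Other called members at 42 weeks came from lists that were not called as a whole. Bile acid synthesis had Cyp8b1, the sterol 12α-hydroxylase, at -1.35 ± 0.19 and the transporter Slco1a4 at -1.12 ± 0.21. Sex-biased genes moved both ways: the elongase Elovl3 at -1.42, Mup21 at -1.21 and Keg1 at -0.60 among male-biased genes, beside the increase in Moxd1. Among female-biased genes, Cyp2c40 stood at -1.74 and Sult1e1 at 0.73. Socs3, an inhibitor of cytokine signalling, rose by 2.47 ± 0.39 (limma adjusted p = 0.0259; 1.83 and no longer called without KKAy array 1, and 3.11 without KKAy array 2; its other probe set stood at 0.87, adjusted p = 0.141), and the insulin receptor substrate Irs1 fell by 0.76 ± 0.13 (adjusted p = 0.0324). The endotoxin co-receptor Cd14 rose by 1.59 and the amino acid enzymes Sds, Sdsl and Uroc1 by 1.58, 0.74 and 0.50. Chac1 of the stress response rose by 0.92, Cebpa by 0.93, collagen Col4a2 by 0.70 and alpha-globin Hba-a1 by 1.61. Mean values of Hba-a1 at 16 and 42 weeks were 11.74 and 9.61 in KKa and 11.29 and 11.22 in KKAy. Glutathione transferase Gstm2 fell by 0.57. Camera gave adjusted p = 0.0718 for macrophage markers, 0.989 for lymphocyte and for stellate cell and matrix markers, 0.649 for cholangiocyte, 0.691 for sinusoidal endothelial and for adipocyte markers, and 0.989 for pancreas, muscle and erythroid markers. For each called list the median, the mean and the test had the same sign, and none of the list calls between the strains held with an estimated correlation.

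Of the 659 calls at 42 weeks 266 changed at least 2-fold, 175 higher and 91 lower; 99 carried no established name, and 95 lay in the unlisted block. Without that block 1102 were called, beside 1103 with an FDR under 0.05 in the authors' deposited table, which held 564 of the 659. An intensity trend gave 1113 and the replicate block 423. Without KKa array 1 limma called 52 probe sets, 47 of them among the 659, without KKa array 2 it called 81 (79 among them), without KKAy array 1 281 (185) and without KKAy array 2 500 (273). Of the genes named above, agouti, Eif2s2, Cxcl1, Cyp2b10, Nrg4, Npas2, Arntl, Cyp2c67, Zfp972, Gask1a, Elovl3 and Cyp2c40 were called without each of the 4 arrays in turn. Fitted to the 4 arrays of the age alone, limma called 0 at 42 weeks, where the fit to all 12 arrays had 6154 probe sets with an unadjusted p under 0.05.

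In KKa liver from 6 to 16 weeks 38 probe sets rose and 106 fell. Serpine2, a serine protease inhibitor, rose 11.8-fold (3.56 ± 0.25, limma adjusted p = 0.00192). Cyp2b10, the chaperone Hspa8 and the protease Capn8 rose 3.05-fold, 3.03-fold and 2.63-fold. Loxl4, a collagen-crosslinking oxidase, fell by 3.12 ± 0.21 (limma adjusted p = 0.00192) and lipoprotein lipase Lpl by 2.62 ± 0.40 (adjusted p = 0.0446). Cyp4a14, Cyp2c68 and the prolactin receptor Prlr fell by 2.39, 1.89 and 1.64. Matrix and stellate cell genes fell and clock genes rose (both adjusted p = 0.0174, and adjusted p = 0.784 with an estimated correlation), with 1 of 11 called, the matrix gene Sparc at -1.17 ± 0.13, and 0 of 17 called. Adjusted over the lists alone 5 matrix genes were lower, and 4 clock genes were higher and 1 lower. Median centring gave 62 higher and 599 lower and cyclic loess 29 and 36. With 1 array left out there were 8 and 25 calls (6 weeks, arrays 1 and 2) or 12 and 6 (16 weeks), of which 7, 13, 7 and 6 were among the 144 of the full fit.

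In KKAy liver over the same interval 207 probe sets rose and 427 fell. Moxd1 rose 24.6-fold (4.62 ± 0.90, adjusted p = 0.0468), Orm3 8.09-fold and Serpine2 7.87-fold, with the melanocortin receptor accessory gene Mrap2 at 2.80 ± 0.18 and the ribonuclease Rnase2a at 2.68 ± 0.48. The call of Moxd1 was lost without any 1 of the 4 arrays, and the change of Orm3 was 2.35, no longer called, without array 1 at 6 weeks and 3.68 without array 2. Loxl4 fell by 3.73 ± 0.21 (limma adjusted p = 0.00175), while Lpl stood at -2.49. Cholesterol synthesis fell across the list (adjusted p = 4.09e-17, and adjusted p = 0.316 with an estimated correlation). Of its 21 genes 18 were called lower over all probe sets and 21 adjusted over the list alone, led by Sqle at -3.10 ± 0.44, Idi1 at -2.91 ± 0.51 and Nsdhl at -2.29 ± 0.35. Lipogenesis fell with 4 called genes, such as Acly at -1.29, and 10 lower and 1 higher adjusted over the list alone (adjusted p = 3.54e-05, and adjusted p = 0.364 with an estimated correlation). Matrix genes fell with 4 called, such as Sparc at -1.79, and 7 adjusted over the list alone (adjusted p = 9.63e-06, and adjusted p = 0.316 with an estimated correlation). Interferon genes fell with 3 called, such as Ifit1 at -1.40, and 10 lower and 1 higher adjusted over the list alone (adjusted p = 0.000305, and adjusted p = 0.316 with an estimated correlation). Lipid droplet genes rose with Plin4 at 2.51 and Apoa4 at 0.81 called and 8 adjusted over the list alone (adjusted p = 0.000805, and adjusted p = 0.316 with an estimated correlation), while Lpl of this list fell.

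Further lists were called in KKAy from 6 to 16 weeks. PPARα targets rose with Pex11a called at 1.10 and 7 adjusted over the list alone (adjusted p = 0.000597, and adjusted p = 0.351 with an estimated correlation). Clock genes rose with 4 called higher, such as Nr1d1 at 2.66 and Usp2 at 1.76, and Npas2 lower at -0.97, and with 9 higher and 1 lower adjusted over the list alone (adjusted p = 0.00338, and adjusted p = 0.354 with an estimated correlation). Acute phase genes rose with Orm3 called and 4 higher and 1 lower adjusted over the list alone (adjusted p = 0.0438, and adjusted p = 0.748 with an estimated correlation). Glycolysis genes fell with Pgd called at -1.09 and 2 adjusted over the list alone (adjusted p = 0.0142, and adjusted p = 0.445 with an estimated correlation), a call lost after cyclic loess at adjusted p = 0.0583. Cell cycle genes fell with Mcm4 and Mcm7 called at -0.89 and -0.82 and 4 adjusted over the list alone (adjusted p = 0.0135, and adjusted p = 0.369 with an estimated correlation). Sinusoidal endothelial markers fell with Lyve1 called at -1.36 and 3 adjusted over the list alone (adjusted p = 0.0116, and adjusted p = 0.335 with an estimated correlation). The strains shared 17 probe sets that rose and 47 that fell in this interval, against 0.221 and 1.27 for independent lists, with Fisher's exact one-sided p = 1.34e-28 and 6.97e-62. Probe sets are not independent, so these p-values are descriptive. The overlap test had been planned for the strain calls only. Centring gave 171 higher and 795 lower, and with 1 array left out there were 62 and 29 calls (6 weeks, arrays 1 and 2) or 8 and 8 (16 weeks), of which 52, 25, 7 and 7 were among the 634 of the full fit.

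From 16 to 42 weeks KKa liver had 1305 probe sets higher and 726 lower. Cyp2a22 rose by 2.17 ± 0.31, Mrap2 and the lipopolysaccharide co-receptor Ly96 each by 2.06 ± 0.18, Zfp972 by 2.04 ± 0.16 and Cyp4a14 by 1.78 ± 0.34. Cyp2b10 fell by 3.06 ± 0.18 (8.36-fold, limma adjusted p = 0.000933), the vault RNA Vaultrc5 by 2.16, the alpha-globins Hba-a2 and Hba-a1 by 2.14 and 2.13 and the pseudogene Mup-ps14 by 1.52. Vaultrc5 is a short RNA, and 27 of 63 probe sets of 5S ribosomal RNA and 9 of 38 of C/D box small nucleolar RNAs were also called lower here, with 0 and 1 higher. The cholesterol list rose (adjusted p = 0.0186, and adjusted p = 0.968 with an estimated correlation), with Lss at 0.83 and Tm7sf2 at 0.52 called over all and 11 of 21 higher adjusted over the list alone. That list call was lost after centring (adjusted p = 0.0717), cyclic loess (adjusted p = 0.153) and in the brighter probe sets alone (adjusted p = 0.421). Centring gave 2748 higher and 360 lower. With 1 array left out there were 355 and 35 calls (16 weeks, arrays 1 and 2) or 18 and 42 (42 weeks), of which 302, 34, 17 and 39 were among the 2031 of the full fit.

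KKAy liver over this interval had 73 probe sets higher and 69 lower. Cyp4a14 fell by 5.22 ± 0.34 (37.3-fold, limma adjusted p = 0.00252), with the related Cyp4a31 at -3.15 ± 0.34 and Cyp4a32 at -2.58 ± 0.41. The glycogen-targeting subunit Ppp1r3c fell by 2.57 and the thioesterase Acot1 by 2.12. Cxcl1 rose 11.9-fold (3.58 ± 0.35, adjusted p = 0.0135), Dbp by 2.19, the NF-κB cofactor Bcl3 and its pathway adaptor Tifa each by 2.16 and the transglutaminase Tgm1 by 2.05. The change of Dbp was 2.79 and 1.59 without array 1 and array 2 at 42 weeks. PPARα targets fell with 5 called and 14 of 22 adjusted over the list alone (adjusted p = 2.92e-11, and adjusted p = 0.222 with an estimated correlation). Lipid droplet genes fell with Plin5 at -1.95 and Plin4 at -1.86 called and 5 lower and 1 higher adjusted over the list alone (adjusted p = 0.0111, and adjusted p = 0.484 with an estimated correlation). Female-biased genes fell with Cyp4a14 called and 4 lower and 1 higher adjusted over the list alone (adjusted p = 0.00246, and adjusted p = 0.222 with an estimated correlation). Cholesterol genes rose with 0 called and 5 adjusted over the list alone (adjusted p = 2.46e-05, and adjusted p = 0.640 with an estimated correlation). Stress response genes rose with 0 called and 8 higher and 2 lower adjusted over the list alone (adjusted p = 0.00207, and adjusted p = 0.542 with an estimated correlation). Neutrophil markers rose with Retnlg called at 1.40 and 3 adjusted over the list alone (adjusted p = 0.00278, and adjusted p = 0.542 with an estimated correlation). The strains shared 17 rising and 5 falling probe sets, against 2.68 and 1.41 for independent lists (Fisher's exact one-sided p = 9.09e-10 and 0.0135). This overlap test is likewise descriptive and was not planned for the age steps. Centring gave 137 higher and 57 lower, and with 1 array left out there were 2 and 1 calls (16 weeks, arrays 1 and 2) or 38 and 283 (42 weeks), of which 2, 1, 19 and 95 were among the 142 of the full fit.

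The strain difference itself was compared between ages. Between 16 and 42 weeks it changed for 168 probe sets, toward KKAy in 62 and toward KKa in 106. Cyp4a14 changed by -7.00 ± 0.48 (limma adjusted p = 0.00262), Cyp4a31 by -3.93 and Cyp2a22 by -3.27, while Cxcl1 changed by 4.02, Bcl3 by 2.65 and Cyp2b10 by 2.46. Between 6 and 42 weeks it changed for 51, with Npas2 at -3.03 ± 0.25 (adjusted p = 0.00758), Arntl at -1.97 and Cyp2b10 at 2.84. Between 6 and 16 weeks 0 probe sets were called in limma, 2332 had an unadjusted p under 0.05, and the count was 0 with an intensity trend, array weights or the replicate block and 1 among probe sets naming 1 gene. For 42 against 16 weeks, there were with 1 array left out 42 and 4 calls (KKa at 16 weeks, arrays 1 and 2), 7 and 22 (KKa at 42 weeks), 10 and 3 (KKAy at 16 weeks) or 5 and 302 (KKAy at 42 weeks). Of these 32, 4, 6, 14, 9, 3, 4 and 119 were among the 168. For 42 against 6 weeks there were 6 and 3 (KKa at 6 weeks), 6 and 24 (KKa at 42 weeks), 11 and 30 (KKAy at 6 weeks) or 23 and 110 (KKAy at 42 weeks), of which 6, 2, 5, 15, 9, 21, 13 and 38 were among the 51. Cyp4a14 kept its call for 42 against 16 weeks, and Arntl its call for 42 against 6 weeks, without each of the 8 arrays. The strain changes of all probe sets correlated across probe sets, which are not independent, at 0.121 between 6 and 16 weeks, -0.036 between 6 and 42 weeks and 0.008 between 16 and 42 weeks.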

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

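The results here were set apart because the strain difference itself changed between ages in a test of that change. The tests of gene lists in these differences, of clock phase and of a single array were chosen after the results were seen, and the clock genes were assigned to their arms after that too.

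Between 16 and 42 weeks the strain difference changed for 168 probe sets in limma. Fatty acid ω-hydroxylases of the Cyp4a family led the genes whose difference turned toward KKa, with Cyp4a14 at -7.00 and Cyp4a31 at -3.93 on the log2 scale. The P450 Cyp2a22 stood at -3.27, the mitochondrial tRNA gene mt-Ty at -2.78 and the thioesterase Acot2 at -2.35. The clock activators Npas2 and Arntl stood at -2.28 and -2.03, Ube2u at -1.91, the endotoxin co-receptor Ly96 at -1.86 and Zfp972 at -1.76. Cyp2c40 stood at -1.49 and the elongase Elovl3 at -1.23. Among genes whose difference turned toward KKAy, the chemokine Cxcl1 stood at 4.02, the NF-κB cofactor Bcl3 at 2.65 and the CAR target Cyp2b10 at 2.46. The immediate early gene Junb stood at 1.91, the kinase Alpk1 at 1.80, the magnesium transporter Slc41a1 at 1.71, the neutrophil gene Retnlg at 1.70 and Zc3h13 at 1.34. Limma's adjusted p for these genes ran from 0.00262 to 0.0470. PPARα targets fell as a list (camera adjusted p = 1.1e-05, and adjusted p = 0.973 with an estimated correlation). Fry called this list lower too (adjusted p = 0.00355). It also called lists that camera did not, all lower. These were female-biased genes (fry adjusted p = 0.0117), NRF2 targets and antioxidant genes (0.0165), and oncofetal and tumour-associated genes (0.0412). Lipid droplet genes and bile acid genes were the others (both 0.0307).

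Between 6 and 42 weeks the strain difference changed for 51 probe sets. Cyp2b10 stood at 2.84, Alpk1 at 2.02, Slc41a1 at 1.85 and Zc3h13 at 1.38. Npas2 stood at -3.03, Ube2u at -2.09, Arntl at -1.97, Cyp2c67 at -1.88, Zfp972 at -1.85, Cyp2c40 at -1.84, Gask1a at -1.68 and Elovl3 at -1.36. Limma's adjusted p for these genes ran from 0.00357 to 0.0494. Lists that fell were cholesterol synthesis (camera adjusted p = 9.33e-08), lipogenesis (0.00156), PPARα targets (0.00638) and interferon response (0.0366), each with adjusted p = 0.764 with an estimated correlation. Acute phase genes rose at 0.0282 (adjusted p = 0.781 with an estimated correlation) and neutrophil markers at 0.0428 (adjusted p = 0.764 with an estimated correlation). Fry called none of these falling or rising lists, with adjusted p from 0.0704 to 0.275.

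Between 6 and 16 weeks limma called 0 probe sets for this change, with 2332 at an unadjusted p under 0.05, but camera called 9 lists, each with adjusted p = 0.479 with an estimated correlation. Fry called none of these 9 lists, with adjusted p from 0.0773 to 0.23. Cholesterol synthesis fell by camera (adjusted p = 3.04e-16), with a median difference of -1.25, as did lipogenesis (1.92e-07, median -0.77), glycolysis (0.00228), matrix genes (0.0339) and the interferon response (0.0439). Acute phase genes rose (3.51e-05), with PPARα targets (0.000471), amino acid catabolism (0.0339) and lipid droplet genes (0.0349).

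The clock genes were weighed further. Of 17 clock genes, 11 driven through E-box or D-box elements and 6 through ROR elements, 14 had at 42 weeks the sign that a shift of clock phase between the strains would give, a count that restates the pattern since the arms were assigned after the values were seen. The arms differed by 2.48 on the log2 scale at 42 weeks, against 0.08 and 0.38 at 6 and 16 weeks. A single aberrant array was argued against, since the smallest difference with 1 of the 4 arrays left out was 2.22. Different phases at collection and a strain effect on the clock itself cannot be told apart, because the hours of collection are not given in the sources used here. Other genes and lists were read on the same 42-week arrays. Whether the hour of collection contributed to their strain differences was not tested and cannot be told here.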

How the results depend on the processing

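The alternative without the unlisted probe sets and all values of the averaged comparison were chosen after seeing the data. Counts are given in the order strain at 6, 16 and 42 weeks, KKa 6 to 16, KKa 16 to 42, KKAy 6 to 16 and KKAy 16 to 42 weeks, and where they moved the change in strain difference from 16 to 42 and 6 to 42 weeks and the averaged comparison. Except where stated, the cause was not tested.

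The probe sets with a mean at or above the median, which leave fewer tests and a variance model fitted anew, gave 2, 349, 1451, 1308, 3901, 1838 and 703 calls, then 1020, 320 and 360. Probe sets naming 1 gene, a set chosen by strain differences, gave 2, 1210 and 3258 for the strains, 1027 for KKa 6 to 16, 1419 and 827 for KKAy, and 2555, 1341 and 1119 for the last comparisons, with 1 for the change from 6 to 16 weeks. An intensity trend gave 145 and 1113 at 16 and 42 weeks, 796 for KKa 6 to 16, 1349 and 355 for KKAy, then 670, 202 and 212. Without the unlisted probe sets there were 124 and 1102 at 16 and 42 weeks, 630 for KKa 6 to 16, 1212 and 486 for KKAy, then 581, 230 and 268. That fit again has fewer tests and a variance model fitted anew, and which of these moved the counts was not tested. Array weights gave 8 at 16 weeks, 312 and 3248 for KKa and 39 for KKAy 16 to 42. Cyclic loess gave 9 at 16 weeks and 65 for KKa 6 to 16. Median centring gave 661 and 3108 for KKa and 966 for KKAy 6 to 16. A log2 change of at least 1 left 266 at 42 weeks, 57 and 309 for KKa, 195 and 90 for KKAy and 7 for the average. An adjusted p of 0.01 left 0, 1, 86, 7, 59, 16 and 4, then 5, 5 and 10.

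Fitted to the compared groups alone, limma called 0 in each of the 7 strain and age comparisons and 0 for the change from 16 to 42 weeks, and 10 for the change from 6 to 42 weeks. Those fits keep 2 or 4 residual degrees of freedom in place of 6, and the counts at an unadjusted p under 0.05 in the fit to all arrays were 1878, 4491, 6154, 6036, 8206, 6449 and 4942. The replicate numbers did not pair the arrays, since replicate differences of the groups correlated at -0.047 to 0.055. With the number as a block there were 0 calls at 6 weeks, 423 at 42 weeks, 45 for KKa 6 to 16, 363 and 77 for KKAy, then 64 and 29, so the overlaps of strain calls at 6 weeks with those at 16 and 42 weeks were 0 by construction, against 1 and 1 without the block. In the brighter probe sets those overlaps were 2 and 2, and the one between 16 and 42 weeks was 49 against 1.

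With 1 array left out, where the lone array is assumed to vary like the others, the calls ranged from 0 to 1, 0 to 5 and 52 to 500 for the strains, 6 to 25 and 18 to 355 for KKa, 8 to 62 and 1 to 283 for KKAy, 3 to 302 and 3 to 110 for the changes and 6 to 89 for the average. The change from 6 to 16 weeks stayed at 0.

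With an estimated correlation 0 gene lists were called in each of the 7 comparisons. For KKa 16 to 42 weeks 0 were called after centring, 0 after cyclic loess and 0 in the brighter probe sets, and for KKa 6 to 16 weeks 1 was called in the brighter probe sets, where the matrix list was lost (adjusted p = 0.215). The brighter probe sets also ended the calls of the lipid droplet list (adjusted p = 0.142) and the female-biased list (0.0563) between the strains at 16 weeks and of glycolysis for KKAy 6 to 16 weeks (0.0594). Neutrophil markers, called at 42 weeks and for KKAy 16 to 42 weeks, had too few members there to test. Over 144 results of named genes there were 2123 values under the alternatives, of which 1456 kept their side of the threshold, 662 lost their call and 5 gained one. Of the results that were called, 0 changed sign. The sign of results not called was not compared. The losses numbered 487 of 840 with 1 array left out, 114 of 144 in the fit to the compared groups, 29 with the block, 19 with array weights, 8 after cyclic loess and 5 after centring. Signal over background is not given in the sources used here, so its limit on dim probe sets is unknown.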

Other observations

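The comparison averaged over ages and the tests of short RNA recovery, of intensity and of linkage were chosen after the data were seen, and only the test on other splits of the arrays was written before its result.

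Averaged over the 3 ages, 46 probe sets were higher and 28 lower in KKAy, 74 in all, with 4370 at an unadjusted p under 0.05. Besides agouti at 1.61 ± 0.08 (log2, n = 6 arrays per strain, limma adjusted p = 0.000443), the growth factor Nrg4 rose by 1.79 ± 0.15 (adjusted p = 0.00803) and the ceramide synthase Cers6 by 0.94 ± 0.11 (adjusted p = 0.0241). The kinase Alpk1 was higher by 0.79, the acute phase gene Orm3 by 1.78, Cyp4a14 by 1.36, Cyp2b10 by 1.23, Retnlg by 0.87, Cd14 by 0.82 and Gpcpd1 by 0.75. Npas2 fell by 1.33 ± 0.10 and Eif2s2 by 0.81 ± 0.06 (both adjusted p = 0.00436). Gask1a was lower at -0.99, Cyp2c67 at -0.87, Zfp972 at -0.75, the cytoskeletal gene Septin9 at -0.73, Arntl at -0.71, the chitinase-like gene Chil6 at -0.70, Hsd3b5 at -0.69 and Cyp2c40 at -0.63. These averages hide unequal ages. Cyp4a14 had strain changes of 1.18, 4.95 and -2.05 at 6, 16 and 42 weeks, Cyp2b10 of 0.16, 0.54 and 3.00, Alpk1 of 0.04, 0.26 and 2.06, Npas2 of -0.06, -0.81 and -3.10 and Arntl of -0.07, -0.01 and -2.04, while agouti had 1.67, 1.49 and 1.68 and Eif2s2 -0.65, -0.65 and -1.14. Agouti, Cyp2b10, Npas2, Eif2s2 and Arntl were called without each of the 12 arrays in turn. With 1 array left out there were 11 and 44 calls (KKa at 6 weeks, arrays 1 and 2), 8 and 15 (KKa at 16), 9 and 6 (KKa at 42), 28 and 14 (KKAy at 6), 10 and 8 (KKAy at 16) or 48 and 89 (KKAy at 42). Of these 10, 25, 7, 12, 9, 6, 20, 12, 10, 8, 29 and 42 were among the 74. Among 100 of the 108 balanced splits of the arrays within ages, 1, the real one with 74 calls, gave as many, and the highest other split gave 42. Most other splits mix arrays of both strains in a group, which can widen the spread and lower the count. The comparison of splits therefore cannot exclude chance. Arrays of a group may share RNA, so it also says nothing of chance between mice or pools, which are too few for such a test.

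Called members of the gene lists in the age steps were named here after their values were seen. In KKa from 16 to 42 weeks the aldo-keto reductase Akr1c18 rose by 1.40, the thioesterase Acot2 by 1.38, the ornithine aminotransferase Oat by 1.22 and the interferon-induced genes Ifit1 and Ifi44 by 1.16 and 0.84. The respiratory chain subunits Ndufa9 and Ndufs1 rose by 0.48 and 0.47, while the carbohydrate-responsive factor Mlxipl fell by 0.91. In KKAy from 6 to 16 weeks Hsd3b5 fell by 1.87 and Keg1 by 0.97, both male-biased, while the female-biased Cyp2b9 rose by 1.25 and Sult1e1 by 0.82. In KKAy from 16 to 42 weeks Cyp8b1 fell by 1.46 and the insulin receptor substrate Irs2 rose by 0.96, and Arntl fell by 1.69 beside a rise of 2.19 in Dbp. All of these passed limma's threshold over all probe sets.

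Probe sets of 5S ribosomal RNA had a median log2 value of 3.96 on the KKa arrays at 42 weeks and 4.38 to 5.00 in the other groups, highest in KKAy at 42 weeks. Of 63 such probe sets 25 were called higher in KKAy at 42 weeks. Shares called at this age are raised by selection, since the authors' 42-week table is among those that named these probe sets. Medians at 42 weeks were 5.87 in KKa and 6.26 in KKAy for C/D box small nucleolar RNAs, 7.19 and 7.96 for H/ACA ones and 3.51 and 3.68 for microRNAs, with 8 of 38, 2 of 13 and 1 of 84 called higher and 0, 0 and 2 lower, though KKa at 42 weeks did not have the lowest median of the 6 groups in these 3 classes. Among 113 short RNA probe sets named by the 6- or 16-week tables, 14 were called higher and 2 lower at 42 weeks. Of the 113, 89 had a positive strain change at 42 weeks. The median change was 0.19, against -0.18 and -0.11 at 6 and 16 weeks, the ages that named them. Their group medians were lowest in KKa at 42 weeks (4.71) and highest in KKAy at 42 weeks (5.33). Lower recovery of short RNA in the KKa arrays could give the positive changes. Intensity-dependent normalization was argued against, since matched probe sets of the same brightness, 20 for each, had a median of 0.01. Recovery and a biological difference in these RNAs cannot be told apart, because no measure of RNA size or yield is given in the sources used here.

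Calls of the averaged comparison lay partly near agouti on chromosome 2. Outside the locus itself, 4 of 203 probe sets within 25 Mb were called (1.97%), against 62 of 8888 elsewhere (0.698%), with a one-sided Fisher exact p of 0.0596. The 4 were the glycerophosphodiesterase Gpcpd1 at 0.75 and Zfp972 at -0.75 (both adjusted p = 0.0300), Zmynd8 at -0.46 (adjusted p = 0.0355) and a probe set with 2 gene names at 0.64 (adjusted p = 0.0241), while within 0.3 Mb 3 of 5 were called, those of agouti and Eif2s2 and one with 2 gene names at -0.74 (adjusted p = 0.0207). The averages hide unequal ages for Gpcpd1 and Zfp972. Mean log2 values of Gpcpd1 in KKa and KKAy were 7.73 and 7.65 at 6 weeks, 7.08 and 8.36 at 16, and 7.39 and 8.44 at 42. Those of Zfp972 were 1.78 and 1.68, 1.57 and 1.38, and 3.61 and 1.65. For the 4 calls outside the locus, donor DNA linked to the yellow allele and unlinked effects cannot be told apart here. These calls were few, and only probe sets in the authors' tables had a position. The calls within the locus did not enter the Fisher test. Sequence variants under the probes were not tested.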
